A study of Mus musculus with 18 samples.

How the data were processed

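RNA was sequenced from neocortex of C57BL/6J mouse embryos at E14.5 after 24 h of culture, with EPIREGULIN in the treated groups. Radial glia (RG), intermediate progenitors (IP) and neurons (N) were isolated from control (Ctl) and treated (Epi) cultures, which gives 6 groups of 3 biological replicates and 18 libraries. Groups and replicate numbers were taken from the sample titles and descriptions. In the characteristics fields the values stood under shifted tags, with the population under a cell line tag and the treatment under a genotype tag, and they matched the titles in every library. RNA was extracted with a kit made for fixed, embedded tissue and libraries were made by SmartSeq2, per the labels' protocols. SmartSeq2 amplifies full-length cDNA, is not stranded and carries no molecular identifiers, so copies made by PCR are counted as reads.

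The deposited values are raw read counts per gene, with one column per library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0, trimmed with cutadapt 2.6 and counted with featureCounts 2.0.1 on GRCm39. The aligner is not given in the sources used here. The table held 55508 rows, of which 55416 were genes and 92 were spike-in sequences, and 1492 gene rows had no symbol. Its header words for strand and gene type were exchanged, which was seen from the values and set right before use. Coordinates are 1-based and on GRCm39, as the table gives them, and symbols and Ensembl identifiers were used as paired there. Total counts ranged from 15.5 to 34.2 M per library.

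Counts were analysed in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16 with the 6 groups, which left 29355 genes, and libraries were scaled by TMM factors. All 18 libraries entered 1 quasi-likelihood fit of the 6 group means, and each comparison was a two-sided contrast of it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values in the text, which are counts scaled to a common library total, were computed from the deposited counts with TMM factors and are means ± SD over the 3 libraries of a group. Log2 fold changes are edgeR estimates ± SE, with 95% intervals from the same fit, which include the spread between replicate libraries.

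The comparisons were Epi against Ctl in each population, their mean over the 3 populations, the differences of the treatment effect between populations, and the 3 pairs of populations in control cultures. For the treatment comparisons, 33 gene lists for cell types, signalling pathways, cell cycle, metabolism and stress were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the 33 lists. The correlation was also estimated from the data, and fry tested whether the genes of each list moved, on balance, one way. Comparisons, tests, lists and the rule for named genes were fixed before the data were examined.

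Genes are named by this rule: adjusted p under 0.05, an ordinary symbol, mean log2 CPM of at least 1 and no overlap between the libraries of the compared groups, then the 12 largest changes in each direction. Where fewer than 10 genes were called, the 10 with the smallest unadjusted p among genes with such a symbol and such a mean are listed as not passing. For each list up to 4 called members with the smallest p serve as examples, and a panel of 23 genes (ERBB receptors, markers of the populations, cycle genes and targets of ERK signalling) is reported whatever its outcome.

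Alternatives were RLE and upper-quartile factors, no filter, the robust form of the edgeR fit, libraries thinned to the smallest total, only the compared groups in the fit, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block over all libraries or within each population, and leaving out each library in turn. A filter at a mean log2 CPM of 3, alone or with the block, and camera with both the block and an estimated correlation were chosen after seeing the data. The labels do not say whether a shared replicate number means a shared culture day. Whether it pairs the libraries was checked on 11210 genes with a mean log2 CPM above 3, after removal of each group's mean. Between Ctl and Epi, libraries of the same number correlated at 0.187 to 0.619 in RG, 0.160 to 0.600 in IP and 0.198 to 0.677 in N, and libraries of other numbers at -0.53 to 0.0969, -0.57 to 0.118 and -0.62 to -0.0226. These correlations are across genes, which are not independent replicates. Among the control populations the same-number correlations were 0.281 to 0.632 for RG and IP and 0.175 to 0.562 for IP and N. Values with the block are therefore given where it changed a call or moved a count of calls by more than 1.5 times.

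The tests were tried on simulated counts drawn from the means and library sizes of the 18 libraries, with 200 of 29355 genes changed. The changed genes were drawn from those with a mean log2 CPM of at least 1, so the shares below do not cover weaker genes. Libraries were drawn independently, without pairing by replicate number. At 2-fold, 75.5% of the changed genes were recovered for Epi against Ctl in RG, 81.5% in IP, 74.5% in N and 98.5% for the mean of the 3 populations. At 1.5-fold the shares were 16.5%, 2.5%, 7.5% and 71.0%. A simulated list of 40 genes raised 1.5-fold in RG had an adjusted p = 2.7e-64, or 4.92e-07 with an estimated correlation, and 0 of the other lists passed. Genes were drawn independently of each other, so this does not show how often a list passes falsely when its genes are correlated. Reads at olfactory receptor genes, which are silent in this tissue, served as the background level: over 1139 such genes, 537 of them tested, the median mean was 0.219 CPM and the 95th percentile 0.760 CPM. These background levels and the summed reads of silent genes are scaled by library totals without TMM factors. The spike-in rows were left out of the fits.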

Results

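Gene expression was measured by RNA sequencing in 18 libraries from neocortex of E14.5 mouse embryos (C57BL/6J). Hemispheres of the brain were kept for 24 h in a rotating culture (HERO), either without additions (Ctl) or with human recombinant EPIREGULIN at 50 ng/mL (Epi). EPIREGULIN is a secreted ligand of the EGF family that signals through EGFR and ERBB4. After culture, 3 populations were isolated: radial glia (RG), the stem cells of the cortical wall, intermediate progenitors (IP), which descend from them and divide away from the ventricle, and neurons (N). How the populations were told apart is not given in the sources used here. Each of the 6 groups held 3 biological replicates. Total counts averaged 26.2 ± 9.64 M in Ctl RG, 26.9 ± 4.63 in Epi RG, 24.2 ± 6.83 in Ctl IP, 26.7 ± 3.08 in Epi IP, 22.4 ± 2.62 in Ctl N and 23.6 ± 2.99 in Epi N (SD, n = 3 each). The most abundant gene took between 1.48% and 3.65% of the counts of a library. Mitochondrially encoded transcripts made up 3.68% ± 0.821 of counts in RG, 6.87% ± 1.64 in IP and 7.31% ± 1.58 in N (SD, n = 6 each).

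The comparison of control IP with control RG asked whether the isolated populations carry the transcripts of the cell types they are labelled as. Radial glial transcription factors were far lower in IP: Hes5, an effector of Notch signalling, stood at 211 ± 14.52 CPM in RG and 6.66 ± 2.39 in IP, and Hes1 at 103 ± 15.7 and 3.08 ± 0.938. Eomes, the transcription factor that marks intermediate progenitors, was higher in IP, at 122 ± 32.7 against 17.4 ± 3.27 CPM, a log2 fold change of 2.80 ± 0.28 (adjusted p = 2.11e-08). The largest differences were those of neuronal genes. Neurod6 went from 2.63 ± 0.641 CPM in RG to 750.0 ± 149 in IP, the microtubule regulator Stmn2 from 4.02 ± 0.686 to 958 ± 125, and Tbr1, a transcription factor of early-born and deep-layer neurons, from 1.78 ± 0.445 to 351 ± 62.7. Hes5 lies on chromosome 4 of GRCm39 (ENSMUSG00000048001, 155045380 to 155046828), Eomes on chromosome 9 (ENSMUSG00000032446, 118307280 to 118315200), Neurod6 on chromosome 6 (ENSMUSG00000037984, 55654807 to 55658248) and Tbr1 on chromosome 2 (ENSMUSG00000035033, 61633274 to 61644458).

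Besides Neurod6, Stmn2 and Tbr1, the genes with the largest higher values in IP were Actl6b, Arpp21, Prdm8, Mir124a-1hg, Mc4r, Clmp, Myt1l, Runx1t1 and Camk2b, with log2 fold changes between 7.17 and 7.49. The genes with the largest lower values were S1pr1, Sall3, Tnc, Ednrb, Ccn1, Tagln2, Hes1, Hes5, Mlc1, Rgcc, Pdpn and Fbln7. S1pr1, a receptor for sphingosine-1-phosphate, had a log2 fold change of -5.39 ± 0.35, and Fbln7, the smallest of them, of -4.77 ± 0.25. Tnc, which encodes the matrix protein tenascin C, stood at 329 ± 35.6 CPM in RG and 8.19 ± 1.43 in IP.

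All 24 radial glia markers were lower in IP, with a median log2 fold change of -3.75, among them Vim (1419 ± 164 to 132 ± 13.3 CPM), Id4, Sox9 and Ttyh1, and 24 passed when adjusted over the list alone. Of 20 intermediate progenitor markers, 14 were higher and 3 lower (18 adjusted over the list alone), with Neurod1 at 1.61 ± 0.18 and 109 ± 21.0 CPM and Elavl2, Nhlh1 and Dll3 also higher. All 26 neuron markers were higher, again with 26 adjusted over the list alone and a median of 5.24, and Myt1l, Snap25, Ina and Crmp1 led them. All 8 markers of Cajal-Retzius cells, the early neurons of the marginal zone that secrete reelin, were higher too (8 adjusted over the list alone): Reln (ENSMUSG00000042453, chromosome 5, 22089452 to 22549700) rose from 4.93 ± 0.664 CPM in RG to 218 ± 21.6 in IP, and Trp73 (log2 fold change 4.86), Lhx5 (4.14) and Lhx1 followed it. Of 16 interneuron markers, 9 were higher and 2 lower (11 adjusted over the list alone), with Sst at 2.49 ± 1.43 and 71.9 ± 30.04 CPM. Of 12 basal radial glia markers, 9 were lower and 1 higher (10 adjusted over the list alone), including Tnc, Acsbg1, Itgb5 and Il6st.

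Proliferation genes were lower in IP without exception among the S phase genes: 60 of 60 (60 adjusted over the list alone), with Mcm3, a subunit of the replicative helicase, at 162 ± 28.8 and 15.3 ± 0.927 CPM. Of 64 mitosis genes, 63 were lower and 1 higher (64 adjusted over the list alone), with a median of -3.28. Mki67, which encodes the proliferation antigen Ki-67, stood at 523 ± 22.4 CPM in RG, 51.0 ± 22.9 in IP and 8.89 ± 0.864 in N. These IP values are those of the population as isolated, which also carried the neuron transcripts given above. They were not resolved into dividing progenitors and neurons, so they do not give the cycling of the progenitors alone. Of 14 genes for D cyclins, their kinases and CDK inhibitors, 9 were lower and 2 higher (13 adjusted over the list alone), with Rbl1, Cdk6, Cdkn2c and Ccnd1 lower. Of 24 Notch pathway genes, 12 were lower and 7 higher (19 adjusted over the list alone), with Hes5, Notch1 and Notch2 lower and Dtx1 higher. Of 12 Hedgehog pathway genes, 10 were lower and 1 higher (11 adjusted over the list alone), Gas1, Cdon, Gli3 and Smo among the lower ones. Of 20 Wnt targets, 9 were lower and 4 higher (13 adjusted over the list alone), with Prdm16 lower and Myc higher.

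Receptors of the EGF family differed between the populations. Erbb2 stood at 54.0 ± 0.789 CPM in RG and 3.78 ± 0.878 in IP (log2 fold change -3.81 ± 0.26, adjusted p = 2.96e-11), and Egfr at 3.51 ± 0.493 and 1.70 ± 0.263 (-1.06 ± 0.26, adjusted p = 0.00215). Erbb4 went the other way, at 2.00 ± 0.357 in RG and 8.39 ± 4.23 in IP (2.07 ± 0.56, adjusted p = 0.00427). Of 18 EGF family ligands, ERBB receptors and their regulators, 6 were higher in IP and 5 lower (11 adjusted over the list alone), with Lrig2, Nrg3 and Hbegf higher, a median of -0.13 and a mean of 0.01. Egfr is on chromosome 11 (ENSMUSG00000020122, 16702203 to 16868158), as is Erbb2 (ENSMUSG00000062312, 98303296 to 98328542), and Erbb4 is on chromosome 1 (ENSMUSG00000062209, 68071345 to 69147218). Ereg, the mouse gene for EPIREGULIN (ENSMUSG00000029377), averaged between 0.182 and 0.387 CPM in every group, within the range of silent olfactory receptor genes. The basal radial glia marker Hopx averaged between 0.0442 and 0.735 CPM, also within it. Of 28 targets and feedback genes of ERK signalling, 13 were lower and 7 higher (21 adjusted over the list alone): Etv4, Etv5 and Hmga2 were lower, and Dusp6, a phosphatase for ERK, was higher, at 7.26 ± 0.491 and 46.4 ± 7.86 CPM. Of 28 immediate early genes, 13 were lower and 8 higher (22 adjusted over the list alone), with Jun and Ccn1 lower and Ier5 and Fosl2 higher.

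Among metabolic lists, 25 of 30 glycolysis and hypoxia genes were lower in IP and 3 higher (29 adjusted over the list alone), with Ldha at 749 ± 15.1 and 275 ± 0.166 CPM and Tpi1, Aldoa and Slc2a1 lower as well. Cholesterol biosynthesis genes went up: 21 of 25 were higher and 0 lower (22 adjusted over the list alone), led by Fdft1, which makes squalene, at 55.7 ± 2.74 and 204 ± 23.1 CPM, with Mvd and Tm7sf2. Of 13 mitochondrially encoded genes, 8 were higher (12 adjusted over the list alone), with mt-Cytb at 8093 ± 1800 and 25236 ± 8434 CPM. Of 60 nuclear genes of oxidative phosphorylation, 13 were higher and 3 lower (14 adjusted over the list alone). Of 78 ribosomal protein genes, 32 were lower and 1 higher (35 adjusted over the list alone), with Rpl12 at a log2 fold change of -1.05 ± 0.13. Of 46 matrix and integrin genes, 24 were lower and 8 higher (33 adjusted over the list alone), with Tnc and Itgb8 lower and Lamb1 and Vcan higher.

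Stress and p53 genes were mostly lower in IP: 14 of 26 genes of the integrated stress response, with Phgdh (309.7 ± 33.8 and 54.9 ± 9.30 CPM), Trib3 and Psat1, and 0 higher (16 adjusted over the list alone), and 16 of 24 p53 targets, with 2 higher (18 adjusted over the list alone), Plk2 among the higher at 12.4 ± 1.01 and 227 ± 28.0 CPM. Heat shock genes split, 5 of 19 higher and 7 lower (12 adjusted over the list alone), as did interferon genes, 5 of 31 higher and 5 lower (10 adjusted over the list alone), with Stat2 higher and Ifitm3 lower. Of 12 mural markers 5 were lower (5 adjusted over the list alone), Notch3 and Pdgfrb among them, and of 8 oligodendrocyte precursor markers 4 were lower (4 adjusted over the list alone), with Olig2 and Cspg4. Of 12 meningeal markers, Fn1, Col1a1 and Dcn were lower (3 adjusted over the list alone). Of 15 endothelial markers 1 was higher and 2 were lower (3 adjusted over the list alone), of 8 choroid plexus markers 1 and 1 (2 adjusted over the list alone). No macrophage, erythroid or sex-linked gene was called (0 of 15, 10 and 5 over all genes, and 0 of each adjusted over the list alone).

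In all, edgeR called 12122 of 29355 genes between IP and RG, 6666 higher and 5456 lower in IP, with 1963 and 1258 of them beyond 4-fold. With upper-quartile factors the median of all genes moved by -0.11 on the log2 scale, and the higher share of the called genes went from 55.0% to 48.0%.

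**Figure D1:**
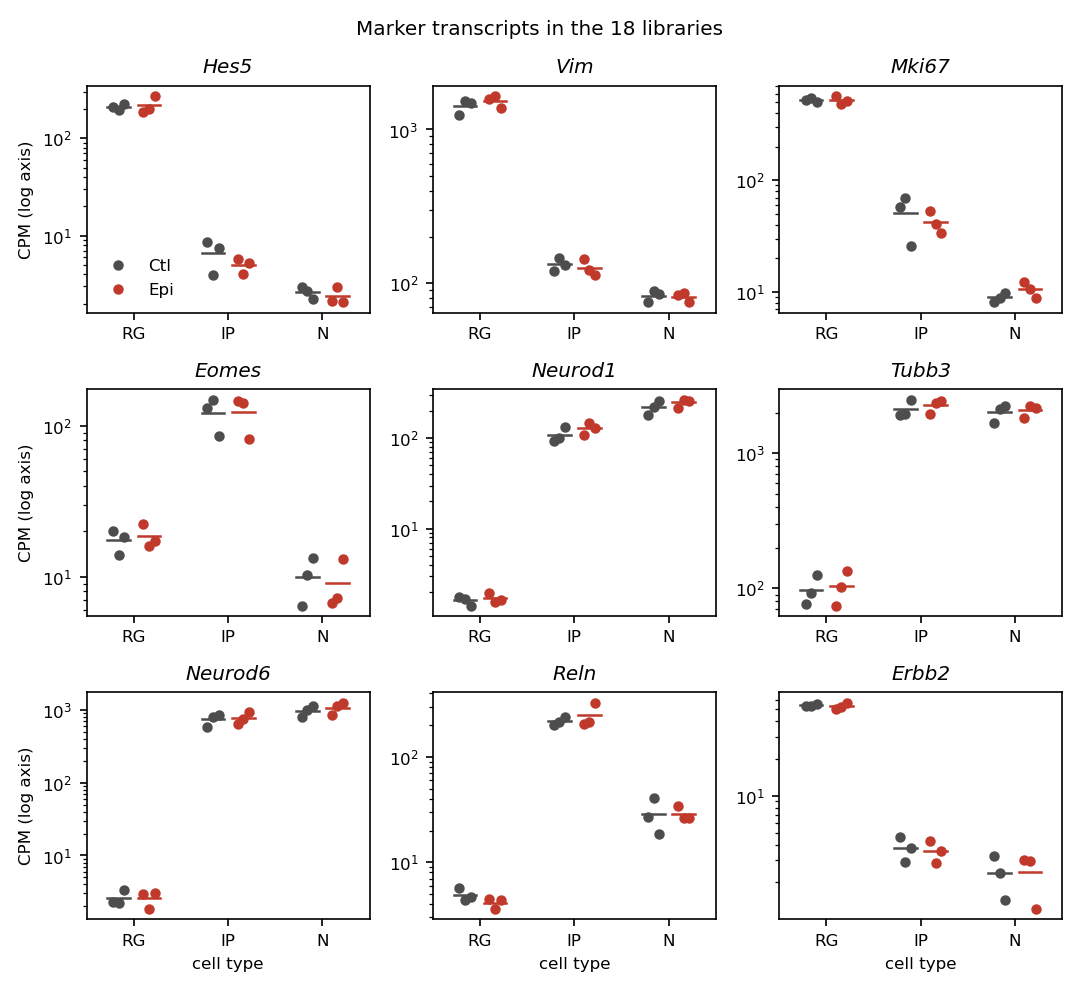
CPM of 9 marker genes on a log axis in RG, IP and N, with a point for each library (Ctl grey, Epi red) and a line at each group's mean (n = 3 libraries). Hes5, Vim, Mki67 and Erbb2 are highest in RG, Eomes and Reln in IP, and Neurod1 and Neurod6 in N.

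The comparison of control N with control IP asked how the neurons differ from the population labelled as their precursors. Eomes was lower in N, at 10.02 ± 3.44 against 122 ± 32.7 CPM (log2 fold change -3.60 ± 0.30, adjusted p = 2.19e-08). The Slit receptor Robo2 stood at 77.0 ± 3.91 CPM in IP and the higher 421 ± 53.9 in N, the netrin receptor Unc5d at 33.5 ± 6.50 and 181 ± 27.3, and the semaphorin co-receptor Nrp1 at 147 ± 16.2 and 601 ± 76.9. Pdzrn3 had the largest higher value, with 7.15 ± 1.04 and 125 ± 24.7 CPM. Reln was lower in N than in IP, at 28.8 ± 11.0 against 218 ± 21.6 CPM (-2.93 ± 0.22, adjusted p = 8.36e-09). Pdzrn3 lies on chromosome 6 (ENSMUSG00000035357, 101126570 to 101354858) and Robo2 on chromosome 16 (ENSMUSG00000052516, 73688727 to 74208713).

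The other largest higher values in N were those of Hbb-y, Glt28d2, Ndst3, Sema6d, Sema3c, Pcdh18, 7SK, Fzd1 and Slc17a6, the vesicular glutamate transporter VGLUT2 (32.0 ± 2.09 and 138 ± 27.0 CPM). Hbb-y, an embryonic globin of red blood cells, stood at 3.96 ± 3.05 CPM in IP and 33.4 ± 28.3 in N (3.04 ± 0.82, adjusted p = 0.0169). Its call was lost with the robust fit, with limma and without Ctl IP 2, Ctl IP 3 or Ctl N 1. The largest lower values were those of Ndufa4l2, Nxph3, Crym, Fam163b, Hs3st4, Pde1a, Cxcl14, Rgs4, Hs3st3b1, Eomes, Brinp1 and Mc4r. Their log2 fold changes lay between -4.14 and -3.54, and Hs3st4, a heparan sulfate sulfotransferase, stood at 112 ± 19.7 and 7.93 ± 4.44 CPM.

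Neuron markers split between these populations. Of 26, 5 were higher in N and 12 lower (21 adjusted over the list alone): Nrp1 was among the higher ones, and Mef2c (444 ± 32.2 and 93.6 ± 41.9 CPM) and the tau gene Mapt (1845 ± 130 and 699 ± 148 CPM) were lower. Of 8 Cajal-Retzius markers, 7 were lower in N (8 adjusted over the list alone), with a median of -2.70, and Trp73, Ndnf and Ebf3 followed Reln. Of 20 intermediate progenitor markers, 10 were lower and 4 higher (16 adjusted over the list alone), with Rhbdl3 and Kif26b lower and Insm1 higher, at 93.0 ± 21.1 and 274 ± 62.1 CPM. Of 24 radial glia markers, 13 were lower and 2 higher (17 adjusted over the list alone), with Aldoc, Notch1, Ddah1 and Mfge8 lower. Of 16 interneuron markers, Sst and Npy were lower and 0 higher (2 adjusted over the list alone). Of 12 basal radial glia markers, 3 were lower, Lifr, Tnc and Ptprz1 (4 adjusted over the list alone).

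Of 64 mitosis genes, 47 were lower in N and 0 higher (52 adjusted over the list alone), with a median of -1.11. Top2a stood at 72.8 ± 27.7 and 14.8 ± 1.43 CPM, and Aurkb and Cdk1 were also lower. Of 60 S phase genes, 36 were lower and 0 higher (42 adjusted over the list alone), with Mcm3, Cdt1, Mcm6 and Clspn lower. In the list of D cyclins and CDK inhibitors, 5 of 14 were lower and 1 higher (8 adjusted over the list alone): Cdkn1a was lower, and Cdkn1b, the inhibitor p27, was higher, at 50.4 ± 7.54 and 102 ± 6.84 CPM. Of 30 glycolysis and hypoxia genes, 23 were lower and 0 higher (25 adjusted over the list alone), with Ldha at 275 ± 0.166 and 92.1 ± 13.4 CPM and Ndrg1, Aldoa and Pdk1 lower. Of 28 ERK targets, 8 were lower and 1 higher (11 adjusted over the list alone), with Dusp6, Etv5, Ets2 and Spry2 lower, and Dusp6 at 46.4 ± 7.86 and 10.6 ± 4.05 CPM. Of 28 immediate early genes, 5 were lower and 1 higher (10 adjusted over the list alone), with Fosl2, Klf6 and Btg2 lower and Jund higher. Of 18 EGF family genes, Lrig3 and Nrg3 were lower and 0 higher (2 adjusted over the list alone). Of 24 Notch pathway genes, 6 were lower and 2 higher (10 adjusted over the list alone), and of 12 Hedgehog genes, Gas1 and Ptch1 were lower (2 adjusted over the list alone). Of 20 Wnt targets, Neurog1, Nkd2 and Ccnd1 were lower (4 adjusted over the list alone), while the median of the list was 0.24 and its mean -0.21. Among 26 genes of the integrated stress response, Ddit3, Slc7a11, Mthfd2 and Shmt2 were higher and 0 lower (8 adjusted over the list alone).

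Of 31 interferon genes, 6 were lower (10 adjusted over the list alone), H2-K1 and Psmb8 among them, and of 24 p53 targets 5 were lower (7 adjusted over the list alone), with Plk2 at 227 ± 28.0 and 56.7 ± 22.2 CPM. Of 46 matrix and integrin genes 7 were lower and 3 higher (13 adjusted over the list alone), with Vcan lower and Adamts1 higher. Of 15 endothelial markers 3 were lower and 1 higher (4 adjusted over the list alone), while the list's median was -0.05 and its mean 0.07. Ndufa4l2 and Notch3 of 12 mural markers were lower (2 adjusted over the list alone; median 0.01, mean -0.24), as were Hspb8 and Dnajb4 of 19 heat shock genes (2 adjusted over the list alone) and Sulf1 of 8 choroid plexus markers (1 adjusted over the list alone). Of 10 erythroid markers Hbb-y was higher (1 adjusted over the list alone). No gene of the oligodendrocyte precursor, meningeal, sex-linked, mitochondrially encoded, oxidative phosphorylation or cholesterol lists was called over all genes or adjusted over the list alone (0 of each).

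The edgeR test called 3035 genes between N and IP, 762 higher and 2273 lower in N, with 73 and 399 beyond 4-fold. With the replicate number as a block the count was 4652, of which 1548 were higher. The higher share was 25.1% with TMM factors, 20.5% with RLE factors and 37.1% with upper-quartile factors.

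**Figure D2:**
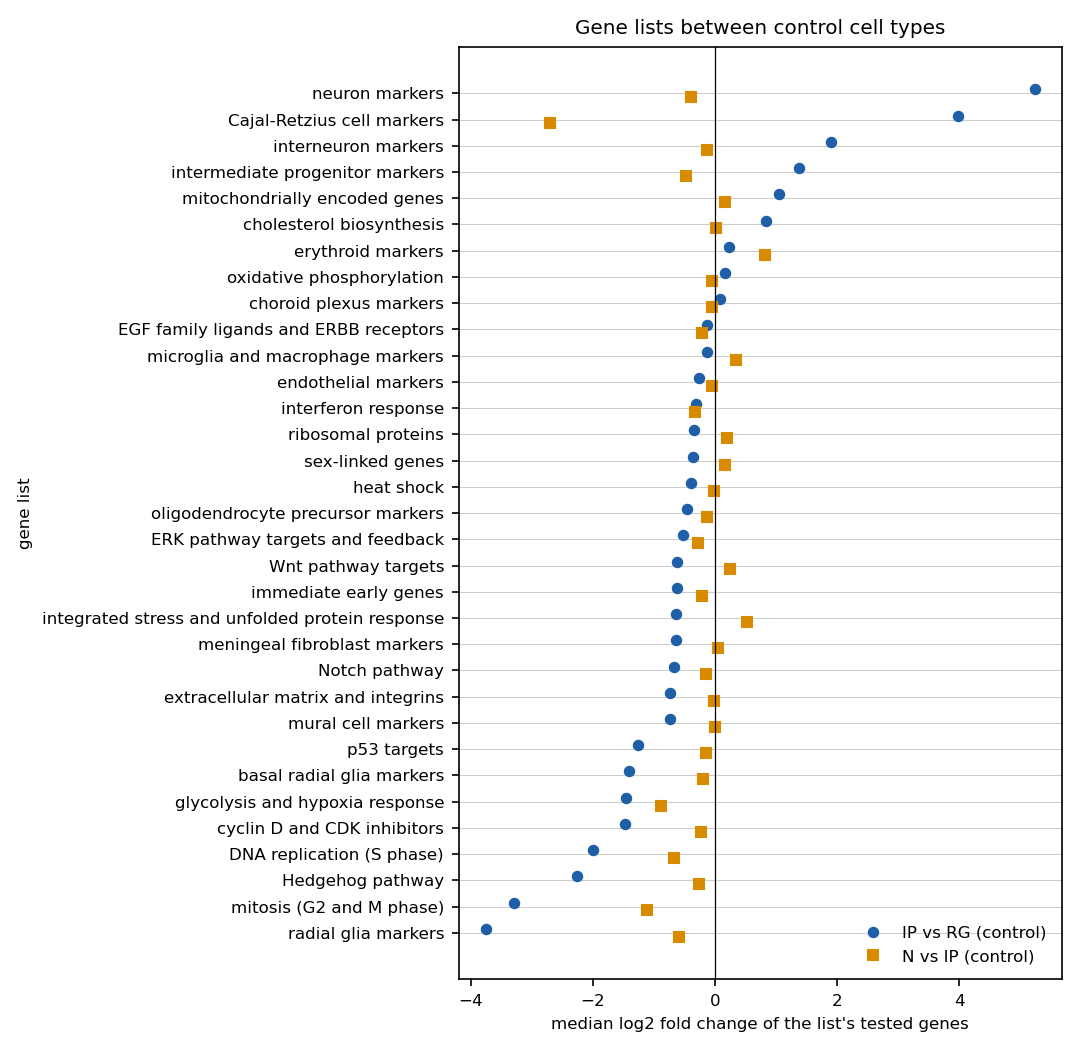
Median log2 fold change of each gene list in control cultures, for IP against RG (blue circles) and N against IP (orange squares), over 3 libraries per group. Mitosis genes lie at -3.28 and -1.11, and Cajal-Retzius markers at 3.98 and -2.70. Medians near 0 flip sign with upper-quartile factors for choroid plexus markers in both comparisons and, in N against IP, for endothelial, matrix, oxidative phosphorylation and heat shock genes, and with RLE factors for mural and cholesterol genes in N against IP.

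Between control N and control RG, the ends of the lineage, Neurod6 had the largest higher value, at 980 ± 175 against 2.63 ± 0.641 CPM. The cell adhesion gene Cntn2 followed with 764 ± 116 against 2.39 ± 1.09 CPM, and Neurod2 stood at 2320.2 ± 231 against 10.7 ± 2.95 CPM. Clmp, Prdm8, Myt1l, Mir124a-1hg, Tbr1, Actl6b, Stmn2, Neurod1 and Slc17a6 completed the 12 largest, down to a log2 fold change of 6.88. The lower values were led by Tnc (-7.20 ± 0.24), the phagocytosis adaptor Mfge8 (-7.10 ± 0.30), Aldoc and Sall3, followed by Igfbp5, the imprinted RNA H19, Mlc1, Rgcc, Zfp36l1, Ccn1, Fbln7 and S1pr1. All 26 neuron markers were higher (26 adjusted over the list alone), 23 of 24 radial glia markers were lower (24 adjusted over the list alone), and 63 of 64 mitosis genes were lower and 1 higher (64 adjusted over the list alone). Of 13 mitochondrially encoded genes, 13 were higher (13 adjusted over the list alone), and of 10 erythroid markers 6 were higher (6 adjusted over the list alone). In all, 11365 genes were called by edgeR, 6168 higher and 5197 lower in N.

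The comparison of Epi with Ctl asked what EPIREGULIN changes in each population, and the study's title puts the proliferation of basal progenitors at its centre. In RG, proliferation markers kept close levels: Mki67 stood at 523 ± 22.4 CPM without and 523 ± 40.4 with EPIREGULIN, Pcna at 153 ± 41.2 and 160.2 ± 25.5, and Ccnd1 at 28.1 ± 2.62 and 28.1 ± 7.75. Stem cell markers were as near, with Sox2 at 314 ± 39.2 and 302 ± 21.0 CPM and Pax6 at 289.7 ± 19.2 and 296 ± 35.8. Among immediate early genes, Fos stood at 40.5 ± 6.41 and 53.2 ± 3.26 CPM (log2 fold change 0.39 ± 0.32, 95% interval -0.26 to 1.05) and Egr1 at 18.6 ± 7.17 and 22.5 ± 4.90. The ERK targets Dusp6 (7.26 ± 0.491 and 7.42 ± 0.712 CPM), Etv5 (76.5 ± 8.13 and 81.3 ± 12.2) and Spry2 (9.94 ± 0.945 and 10.5 ± 1.75) and the receptor genes Erbb2 (54.0 ± 0.789 and 53.2 ± 3.07) and Egfr (3.51 ± 0.493 and 3.05 ± 0.449) did not pass either. No gene of the panel passed in RG (adjusted p = 1.00 for each of these).

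Nuclear genes of oxidative phosphorylation shifted up together by a small step in RG: 58 of 60 had positive fold changes, with a median of 0.12 (camera adjusted p = 9.7e-07, and adjusted p = 0.870 with an estimated correlation). The same held for S phase genes (55 of 60 positive, median 0.06, adjusted p = 0.0373), cholesterol biosynthesis (22 of 25, median 0.10, adjusted p = 0.0437) and glycolysis and hypoxia genes (26 of 30, median 0.08, adjusted p = 0.0437). Mitochondrially encoded genes lay lower, with 13 of 13 negative and a median of -0.19 (adjusted p = 0.0437). For each of these 4 further lists, adjusted p = 0.870 with an estimated correlation. All 5 calls were lost with fry (adjusted p = 0.950 each) and without Ctl RG 1 (0 lists called). With upper-quartile factors the median of all genes in RG moved by -0.046, which is not small beside these medians, though the 5 lists kept their sign. In the same 3 pairs of RG libraries, the summed reads at olfactory receptor genes were lower in the treated one (518 to 409.6, 509 to 354 and 331 to 309 CPM). No single member of the 5 lists passed, over all genes or adjusted over the list alone (0 genes in both). The mitosis list did not pass (30 of 64 positive, adjusted p = 0.978), nor did intermediate progenitor markers (0.853), basal radial glia markers (0.450), EGF family genes (0.505), ERK targets (0.346) or immediate early genes (0.158). Of these lists' genes, 0 passed adjusted over the list alone. In the interneuron list 1 gene did: Gsx2, named after its values were seen, at 2.88 ± 0.238 and 0.692 ± 0.611 CPM (0.0111 adjusted over the list alone).

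Over all genes in RG, 0 of 29355 passed with edgeR, 0 with the replicate block and 0 with limma, and 478, 783 and 1115 had an unadjusted p under 0.05. DESeq2, run here and below on the 53128 genes with a read, called 0, with 631 under 0.05. The edgeR share under 0.05 without the block was 1.63% in RG, 1.82% in IP, 2.56% in N and 2.86% for the mean of the 3 populations. Each of these is below the 5% that uniform p-values would give. The fit without the block, which also gave the intervals here and below, takes no account of the correlation between same-number Ctl and Epi libraries. With the block more genes lay under 0.05, at 783, 952, 1211 and 1483 in the same order. Among genes with an ordinary symbol and a mean log2 CPM of at least 1 in the compared groups, the 10 with the smallest unadjusted p, none passing, were Galnt10 (2.66 ± 0.954 and 4.63 ± 0.460 CPM, edgeR unadjusted p = 0.00162), Cdh11, Slc25a14, Fbxo41, B4galnt1, Arhgap20, Rims1, Cyp2u1, Malt1 and Ccser1. Among 16079 genes with a mean log2 CPM of at least 1, the 95% interval excluded a 2-fold change for 95.2% and a 1.5-fold change for 70.9%. With the block the lists of endothelial (adjusted p = 0.0481) and erythroid markers (adjusted p = 0.00187) were also lower, with adjusted p = 0.728 and 0.301 with an estimated correlation.

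In IP, Eomes stood at 122 ± 32.7 CPM without and 123 ± 35.4 with EPIREGULIN, a log2 fold change of 0.01 ± 0.26 with a 95% interval of -0.53 to 0.55. Mki67 stood at 51.0 ± 22.9 and 42.3 ± 10.1 CPM (-0.26 ± 0.23, interval -0.74 to 0.21), and without Ctl IP 2 its fold change was 0.02. Dusp6 stood at 46.4 ± 7.86 and 51.6 ± 1.59 CPM (0.16 ± 0.19) and Tbr1 at 351 ± 62.7 and 380.4 ± 34.8 CPM, and none of the panel passed. Mitosis genes lay slightly lower together, 48 of 64 with a negative fold change and a median of -0.09 (camera adjusted p = 0.0447, adjusted p = 0.990 with an estimated correlation). Choroid plexus markers, genes of the epithelium that makes cerebrospinal fluid, were negative in 8 of 8, with a median of -0.27 (adjusted p = 0.0447, adjusted p = 0.990 with an estimated correlation). With the block these were adjusted p = 0.0738 and 0.113, so both calls were lost, as they were with fry (adjusted p = 0.982 each). S phase genes (adjusted p = 0.826), intermediate progenitor markers (0.996), basal radial glia markers (0.947) and ERK targets (0.909) did not pass, and 0 genes of any of these lists passed adjusted over the list alone.

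The IP gene test with edgeR called 0 of 29355 genes, as did the block and limma, with 535, 952 and 528 genes at an unadjusted p under 0.05, and DESeq2 called 0 of 53128, with 788. Among genes with an ordinary symbol and a mean log2 CPM of at least 1 in the compared groups, the smallest unadjusted p was that of Ythdc1, a nuclear reader of N6-methyladenosine in RNA, at 163 ± 11.3 and 118 ± 10.2 CPM (-0.47 ± 0.12, unadjusted p = 0.00107, adjusted p = 1.00). Parp9, Cox6b2, Adgrb1, mt-Tq, Shank3, Eif3j2, Dct, Mtrf1l and Sh3d19 followed, none passing. The 95% interval excluded a 2-fold change for 95.05% of the 16079 genes, and a 1.5-fold change for 69.3%. The control IP libraries also carried the neuron and Cajal-Retzius transcripts given above. Tubb3 stood at 1912, 1970 and 2502 CPM in them, against 1674, 2120 and 2234 in Ctl N. Neurod6 stood at 581, 809 and 860 CPM, against 796, 996 and 1146. The IP values are thus those of the population as isolated, and were not resolved into dividing progenitors and neurons.

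In N, the neuron markers Tubb3 (2009.5 ± 296 and 2081 ± 215 CPM) and Tbr1 (270.3 ± 19.5 and 280.7 ± 27.4 CPM) stayed near their control levels. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, had the smallest unadjusted p of the panel, at 1.45 ± 0.187 and 0.564 ± 0.0601 CPM (-1.36 ± 0.32, edgeR unadjusted p = 0.000393, adjusted p = 1.00). It passed adjusted over the list alone (0.0110), the 1 gene of the 28 ERK targets to do so, and its treated level was under the 95th percentile of silent genes. Spry2 (5.10 ± 0.764 and 5.21 ± 0.853 CPM) and Dusp6 (10.6 ± 4.05 and 12.2 ± 0.847) did not follow it, and the ERK list as a whole did not pass (adjusted p = 0.965). Microglia and macrophage markers lay lower, with 12 of 15 negative and a median of -0.44 (adjusted p = 0.0301, adjusted p = 0.977 with an estimated correlation and 0.994 with fry). Of the 15, 4 were above the 95th percentile of silent genes. In the same 3 pairs of N libraries, the summed reads at olfactory receptor genes were also lower in the treated one (488 to 375, 349 to 256 and 349 to 334 CPM). Pdgfrb, a pericyte receptor named after its values were seen, passed adjusted over the mural list alone (0.0373), at 1.05 ± 0.295 and 1.90 ± 0.441 CPM. Spry4 is on chromosome 18 (ENSMUSG00000024427, 38719300 to 38734468).

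For N as well, edgeR called 0 of 29355 genes, and so did the block and limma, with 752, 1211 and 1043 genes at an unadjusted p under 0.05, and DESeq2 called 0 of 53128, with 1014. Cast, the inhibitor of calpain proteases, had the smallest, at 3.45 ± 0.422 and 1.70 ± 0.398 CPM (-1.02 ± 0.22, unadjusted p = 0.000145, adjusted p = 1.00). Under the same limits on symbol and mean, Dusp10, Zswim7, Prorp, Rpl17-ps8, C1qtnf4, Iqgap2, Cacna1f, Tcf7l2 and Gem came next, none passing. The interval excluded a 2-fold change for 93.5% of the 16079 genes, and a 1.5-fold change for 67.6%. With the block, erythroid markers were lower (adjusted p = 5.41e-06, 0.0341 with an estimated correlation and 0.137 with fry) and mitochondrially encoded genes higher (adjusted p = 0.00794, and adjusted p = 0.890 with an estimated correlation).

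The mean effect over the 3 populations, which sets 9 treated against 9 control libraries, asked for a shared response. Between control populations, same-number libraries correlated at 0.281 to 0.632 (RG and IP), 0.175 to 0.562 (IP and N) and 0.0946 to 0.604 (RG and N). The 9 libraries of an arm may thus not be 9 independent units, though the SEs and intervals below treat them so. Ythdc1 again had the smallest p under the limits on symbol and mean, with a mean log2 fold change of -0.26 ± 0.07 (edgeR unadjusted p = 0.00152, adjusted p = 1.00), and Hmga2, a chromatin protein of young radial glia, stood at -0.35 ± 0.10. The others were Vmn2r76, Platr10, Pcdhb16, Rab40b, Xlr3b, Chrna4, Lpar1 and Cast, none passing. Macrophage markers lay lower (12 of 15, median -0.34, adjusted p = 0.00765, adjusted p = 0.965 with an estimated correlation), and 0 of them passed over all genes or adjusted over the list alone. This call was lost with fry (adjusted p = 0.989) and without Ctl RG 1 (0 lists called). Summed reads at olfactory receptor genes were also lower in the treated library of 8 of 9 pairs. With edgeR 0 of 29355 genes passed, as with the block and limma, and 841, 1483 and 1219 had an unadjusted p under 0.05, while DESeq2 called 0 of 53128, with 1158. The interval excluded a 2-fold change for 99.7% of the 16079 genes and a 1.5-fold change for 94.1%. With the block, erythroid markers (adjusted p = 5.38e-06, 0.0357 with an estimated correlation and 0.112 with fry) and the list of sex-linked genes (adjusted p = 0.00499, and adjusted p = 0.248 with an estimated correlation) were lower. That list joins Xist with Y-linked genes, and Xist, 1 of its 5 genes, lay above 0 (0.24 ± 0.08, adjusted p = 0.966). Its call is therefore not a shift of all its members one way. Cholesterol (0.00547, 0.842 estimated) and glycolysis genes (0.0143, 0.974 estimated) were higher with the block.

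The difference of the treatment effect between populations was tested directly. For IP minus RG, N minus RG and N minus IP, edgeR called 0 genes, and so did the block, DESeq2 (of 53128) and limma. In the order edgeR, block, DESeq2 and limma, the genes at an unadjusted p under 0.05 numbered 442, 737, 686 and 717 for IP minus RG, 478, 802, 758 and 950 for N minus RG, and 512, 770, 837 and 564 for N minus IP. Mki67, Eomes and the receptor genes were not called in any of them.

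**Figure D3:**
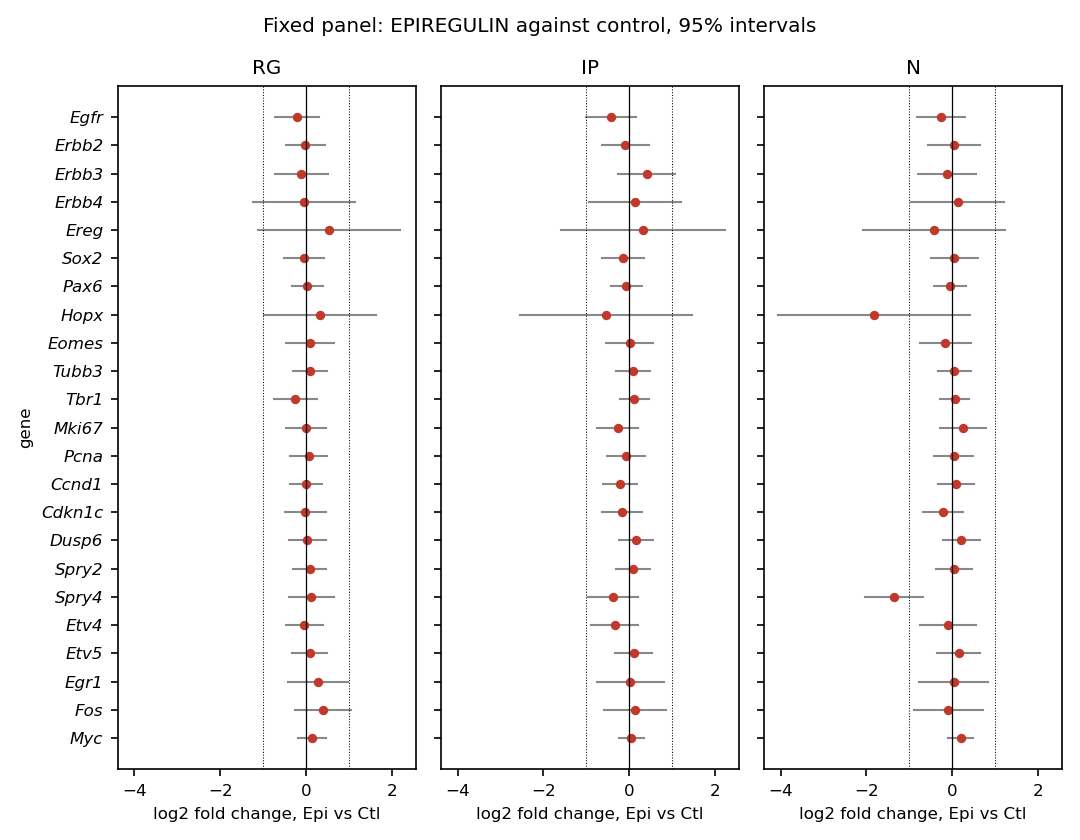
Log2 fold change of the 23 panel genes between Epi and Ctl in RG, IP and N, with 95% intervals from the edgeR fit (n = 3 libraries per group) and dotted lines at 2-fold. The interval of Spry4 in N, -2.03 to -0.69, lies below 0, and Mki67 in RG and Eomes in IP lie near 0.

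**Figure D4:**
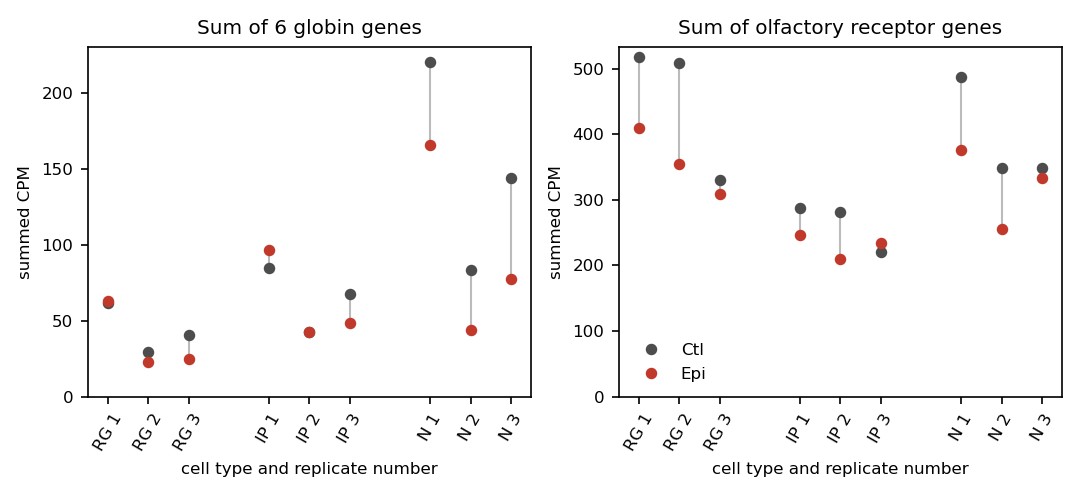
Summed CPM of 6 globin genes (left) and of the olfactory receptor genes (right) in the control and treated library of each population and replicate number, with a line for each of the 9 pairs on a linear axis from 0. The treated library is lower in 7 of 9 pairs for globins and in 8 of 9 for olfactory receptor genes.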

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

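No test in this part was chosen after its result was seen. Reads at the spike-in sequences, which no comparison used, numbered 7 in Epi RG 1, above the 1 to 5 reads of the control libraries, and that library held 31024273 counts in all. A signal in sequences outside the gene counts is what drew attention to it. The difference is 2 reads over the highest control library. As a share of its counts it was 2.26e-05%, under the 3.05e-05% of the control library Ctl IP 2, so it does not stand out once depth is counted. No explanation was tested.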

How the results depend on the processing

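A filter at a mean log2 CPM of 3 and camera with the block and an estimated correlation were chosen after the result was seen. Genes called for Epi against Ctl stayed at 0 in each population, their mean and their differences under each alternative run for them, including each library left out; the filter was not run for the differences, nor the fit of only the compared groups for the mean. Genes called between control populations ranged, one library left out, from 10836 to 11487 (IP and RG), 2229 to 2814 (N and IP) and 10132 to 10764 (N and RG). With the replicate block N against IP had 4652 called genes against 3035, and the block moved no other gene count by over 1.5 times. For RG and N in control the same-number correlations were 0.604, 0.0946 and 0.503, the highest other-number one was 0.0766, and the block gave 13140 called genes against 11365. Of 72 called results for named genes, 5 of 1080 values lost the call, all of Hbb-y in N against IP (3.04 robust, 2.45 limma; 2.69 without Ctl IP 2, 2.84 without Ctl IP 3, 2.16 without Ctl N 1), and 0 reversed. List counts depended on the settings: RG 5, IP 2, N 1 and mean 1 became 0, 0, 0 and 0 with an estimated correlation, 0, 0, 0 and 0 with fry, and 7, 0, 3 and 5 with the block. With block and estimated correlation they were 0, 0, 1 and 1. One library left out gave 0 to 9 in RG (0 without Ctl RG 1, 9 without Ctl RG 2, 2 without Epi RG 3), 1 to 5 in IP (4 without Ctl IP 2, 5 without Ctl IP 3, 1 without Epi IP 1 or 3), 3 to 5 in N (3 without Ctl N 1, Ctl N 2 or Epi N 3, 4 without Ctl N 3 or Epi N 2, 5 without Epi N 1) and 0 to 6 in the mean. In the mean they were 0 without Ctl RG 1, 2 without Ctl IP 1, Epi IP 1 or Epi IP 3, 3 without Epi RG 1 or Epi N 2, 4 without Ctl RG 3, Ctl IP 2, Epi IP 2 or Ctl N 2, 5 without Ctl RG 2, Ctl IP 3 or Ctl N 3 and 6 without Epi RG 2 or Epi N 1. Of 2623 values for 132 named results that were not called, 17 changed sign by more than the SE of the main estimate, all in panel genes, and the cause was not tested; smaller changes of sign are not counted here. With one library left out the log2 fold changes ranged, in RG, for Tubb3 from -0.15 to 0.31, Tbr1 -0.47 to 0.0241, Ccnd1 -0.24 to 0.17, Cdkn1c -0.31 to 0.24 and Spry4 -0.17 to 0.34, in each case reversed without Epi RG 3. In IP they ranged for Erbb4 from -0.48 to 0.61 (reversed without Epi IP 3), Mki67 -0.59 to 0.0246 and Etv5 -0.11 to 0.31 (without Ctl IP 2), Etv4 -0.55 to 0.0259 (without Ctl IP 3) and Fos -0.29 to 0.51 (without Epi IP 1). In N they ranged for Erbb4 from -0.56 to 0.87 and Sox2 -0.42 to 0.43 (without Epi N 2), and for Ereg -1.01 to 0.94, Pax6 -0.19 to 0.25, Dusp6 -0.0770 to 0.46 and Egr1 -0.37 to 0.63 (without Ctl N 3). Hopx in IP was -0.55, and 0.45 with limma, with a range of -1.76 to 0.29 with one library left out. At these depths a 1.5-fold change in 1 population was mostly missed in simulated counts (2.5% to 16.5% recovered). The changed genes there all had a mean log2 CPM of at least 1.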

Other observations

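In this part, the tests on N-type neurons in the IP libraries and less blood-derived RNA were chosen after the result was seen. So were those on the silent gene background and the globin background. The tests on TMM scaling, Cajal-Retzius cells, macrophages and splits of the libraries were chosen before. The sign-flip tests on summed reads of globin and silent genes were not part of the plan fixed before the data were examined. Xist, transcribed from the inactive X chromosome of female cells, averaged 148 CPM over the 6 libraries of replicate number 1, 280 over those of number 2 and 268 over those of number 3. The Y-linked genes Ddx3y (54.3, 33.5 and 30.8 CPM) and Eif2s3y (63.9, 38.8 and 32.8 CPM) ran the other way. All 18 libraries held both kinds of transcript.

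The IP libraries carried Cajal-Retzius transcripts, with Reln at 218 ± 21.6 CPM against 28.8 ± 11.0 in N and 4.93 ± 0.664 in RG (n = 3). Neurons of the N kind carried over into IP would not alone give levels above those of N, and 7 of 8 markers were called higher in IP. That count restates the pattern and was known when the test was chosen, so it adds no independent support. Carry-over as a source of the other neuron transcripts in IP, such as Tubb3 and Neurod6, was not tested. The choice of TMM factors does not account for the Cajal-Retzius difference, since at least 7 of 8 were called higher in IP with RLE and with upper-quartile factors. Those factors moved the median of all genes in N against IP by only -0.04 and 0.07 on the log2 scale, so scaling was varied over a narrow range. Cajal-Retzius cells isolated with the IP cells might, but the test could not settle it: of 3 further genes of these cells, 2 were called higher in IP than in N, Nhlh2 (53.5 against 14.0 CPM, edgeR adjusted p = 2.66e-06) and Ebf2 (2.91 against 1.25 CPM, adjusted p = 0.0194), and Ebf1 was not (adjusted p = 0.974).

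Summed globin transcripts were lower in the treated library of 7 of 9 pairs, with a mean log2 ratio of -0.40 (SD 0.41, exact sign-flip p = 0.0273, adjusted p = 0.0410 over 3 measures; 0.25 by the 3 replicate numbers, the smallest that 3 allow). With the replicate block, 6 of 6 globin genes lay below 0 in RG and N and 3 of 6 in IP. Less blood-derived RNA in the treated libraries stays open: outside the globins only Alas2 of the erythroid markers lay above the 95th percentile of silent genes, and 0 of this 1 gene had a mean log2 fold change below 0 (0.07 ± 0.13), too few to decide. For the N pairs, a lower background of reads at silent genes does not account for the fall. The fall there was at least 6.78 times the level that 6 genes at the background's 95th percentile in Ctl N (0.970 CPM) would hold. The RG and IP pairs were not tested in this way, and for replicate number 2 of IP the sum went only from 42.5 to 42.3 CPM. Reads shared between paralogs such as Hba-a1 and Hba-a2 fall within the sum, and an effect of EPIREGULIN on blood cells was not told apart from handling.

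Reads at olfactory receptor genes were lower in the treated library of 8 of 9 pairs, with a mean log2 ratio of -0.27 (SD 0.20, exact p = 0.0117, adjusted p = 0.0352; 0.25 by the 3 numbers). A library background shared by genes silent in this tissue may explain it, as 7 of 9 pairs were lower for 449 genes of other silent families too (mean -0.21, exact p = 0.0430, adjusted p = 0.0430; 0.5 by the 3 numbers). Fewer macrophages in the treated libraries stay open: the median of the macrophage markers, -0.34, lay at percentile 28.3 of 10000 random sets of olfactory receptor genes, but only 4 of the 15 markers were above the 95th percentile of silent genes, so this test cannot separate the 2.

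The 6 libraries of a comparison can be divided in 10 ways, the real one included, too few for a share under 0.05. A real count of 0 is reached by each division, so the 10 of 10 for genes in RG (highest other 0), IP (highest other 2) and N (highest other 7) say nothing about chance. Between control populations the real counts of 12122, 3035 and 11365 were reached by 1 split each, the real one, with 0 the highest other. For gene lists, 6 splits in RG had at least the real 5 (highest other 14), 10 in IP at least 2 (highest other 16) and 10 in N at least 1 (highest other 14). Among the 4 splits that part all 3 pairs, the highest others were 10, 4 and 5 lists. Over 100 splits drawn, the mean effect had 0 called genes with 100 as large (highest other 346), and the differences IP minus RG, N minus RG and N minus IP had 0 each with 100 as large (highest others 2, 3 and 728), which says as little, the real counts being 0. For lists of the mean effect, 97 of 100 splits reached the real 1 (highest other 14). The splits were not run with the replicate block, with which the real count was 5. The 346 and 728 point to a structure of the samples. In the 10-way splits of Epi and Ctl, called genes (up to 2 in IP and 7 in N) came only from splits that left pairs together. Splits that parted all 3 pairs had 0. Since same-number libraries correlated, splits that leave pairs together are not a neutral reference. Whether the replicate numbers also gave the 346 and 728 was not tested.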
